A study of Caenorhabditis elegans with 12 samples.

How the data were processed

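RNA from whole Caenorhabditis elegans was sequenced from 2 wild isolates, N2 (Bristol, the reference strain) and CB4856 (Hawaii). Synchronized first-stage larvae were raised on Escherichia coli HT115, with doxycycline at 15 µg/mL or without it. Doxycycline is a tetracycline antibiotic that also blocks translation in mitochondria. The worms were collected 50 h later, and the labels name them as larvae of the fourth stage. Strain and treatment gave 4 groups of 3 libraries, named here N2 control, N2 doxycycline, CB4856 control and CB4856 doxycycline. The labels give 1 harvest date and 1 start time for all 12 libraries, so they define no batch. All 12 RNA samples had an RNA integrity number of 10, and total RNA was sequenced on a BGISEQ-500.

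Per the labels, the authors checked reads with FastQC and aligned them with STAR (version written as 2.73a) to WBcel235, also called ce11. The labels also name edgeR 3.24.3, without saying for which step. The deposited values are counts, that is, whole reads per gene with no normalization, 1 file per library. Each file starts with 4 summary lines (unmapped, multimapped, no feature, ambiguous) and then lists 46739 gene identifiers, with a count that ignores strand and a count for each strand. The annotation release, trimming and read filters behind them are not stated. The unstranded column (column 2) was used by a rule that preferred a strand-specific one only if it held at least 90% of the reads of both strands. The larger strand share lay between 51.0% and 52.4%.

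Gene symbols and positions came from a WBcel235 annotation of Ensembl. It held 46484 of the 46739 identifiers, and 43729 had a symbol. Coordinates are those of WBcel235, counted from 1. Members of the 46 gene lists were matched by symbol, synonym or sequence name. The 12 protein-coding genes of mitochondrial DNA carry no usual symbol in that annotation. They were matched by place (at least 90% overlap) to the RefSeq gene models of the mitochondrial genome, a step added after the counts had been seen, and are printed with RefSeq names such as COX1 and ND1. No gene was found for 12 list names (cco-1, cco-2, gfm-2, wars-2, mars-2, hars-2, hsp-16.11, hsp-16.49, daf-21, atg-11, ssp-11 and opt-2).

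Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts were kept by filterByExpr with the 4 groups, which left 15750 genes, and libraries were scaled by TMM (trimmed mean of M values). The quasi-likelihood test (glmQLFit, glmQLFTest) was run on 1 fit of all 12 libraries with a mean per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15750 genes. The comparisons were doxycycline against control within N2 and within CB4856, the difference between these responses (the interaction), and CB4856 against N2 without and with doxycycline. Fold changes are log2, with the second-named group or control as the denominator. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Normalized read counts are the TMM-scaled values of the cpm function of edgeR (CPM), given as mean ± SD of 3 libraries. All tests were two-sided.

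Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes, and adjusted over the 46 lists of a comparison. Camera asks whether a list moved relative to all other genes. Camera with an estimated correlation and fry, which asks whether the list's genes moved on balance in 1 direction, were run beside it. The lists cover mitochondrial, metabolic, stress, immune, protein turnover, cell cycle, cuticle, germline, sperm, yolk and tissue markers, gene families that vary between wild isolates, and genes known to differ in function between N2 and CB4856.

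Named genes followed a rule. In each of the comparisons other than the strains with doxycycline, they were the 6 genes with the largest increase and the 6 with the largest decrease. These had a call, a symbol, a mean CPM of at least 5 and groups without overlap (not required for the interaction), with at most 2 per family and direction. To these were added the 2 members with the smallest p in each list past camera, taken from the 10 lists with the smallest p where more than 20 genes would result. Always named were hsp-6, hsp-60, atfs-1, COX1, ND1, vit-2 and the measured genes of the strain-polymorphism list. The comparisons, tests, lists, naming rule and 15 of the 17 alternative settings, besides leaving out each library, were fixed before the data were examined.

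Alternatives were RLE and upper quartile scaling, scaling without stage-dependent lists or without mitochondrial DNA, no low-count filter, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, only the compared groups in the fit, replicate number as a block, a strand-specific column (column 3), a log2 fold change above 1, an adjusted p under 0.01, estimated correlation and fry. Leaving out each of the 12 libraries in turn completed them. Chosen after seeing the data were 2 more, the mean of the oocyte list per library as a covariate, and leaving out the replicates 3 of N2 control and N2 doxycycline together.

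Reads in genes per library were 17412163 to 22354706. A floor of 3 counts per library was used where all libraries of a group had 0 counts, and folds are then lower bounds. Intervals and floors cover counting error only. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 61 and 87 of them for doxycycline in N2, 61 and 97 in CB4856, 51 and 77 for the interaction, 53 and 89 for untreated strains, and 69 and 88 for treated strains. False calls were 8 of 156, 6 of 164, 12 of 140, 9 of 151 and 5 of 162. The simulated test did not cover DESeq2, limma-voom or fry. Its changed genes were few and rose and fell in equal number, whereas doxycycline gave calls for 77.7% of genes in N2 and 84.1% in CB4856. Its recovery and false calls therefore do not show how TMM behaves under changes that wide. Raw reads, transcript isoforms and sequence variants were not analysed here.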

Results

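Total RNA was the stated material of 12 whole-worm libraries in 4 groups of 3. Reads in genes per library numbered 17412163 to 22114469 in N2 control, 21664102 to 21981644 in N2 doxycycline, 22131089 to 22354706 in CB4856 control and 21320924 to 21517600 in CB4856 doxycycline. At these depths a floor of 3 counts per library corresponded to 0.128 to 0.185 CPM. The first principal component of log2 CPM held 69.1% of the variance and parted treated from untreated libraries, and the second held 20.9% and parted the strains. Correlations across genes were 0.979 to 0.994 within groups and 0.793 to 0.960 between groups. Oocyte markers were low and cuticle and sperm markers high in treated libraries, and these markers also varied among replicates. The mean of the oocyte list was 9.42 to 9.59 (log2 CPM) in N2 control, 7.67 to 8.41 in N2 doxycycline, 9.67 to 9.84 in CB4856 control and 7.56 to 8.19 in CB4856 doxycycline.

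**Figure D1:**
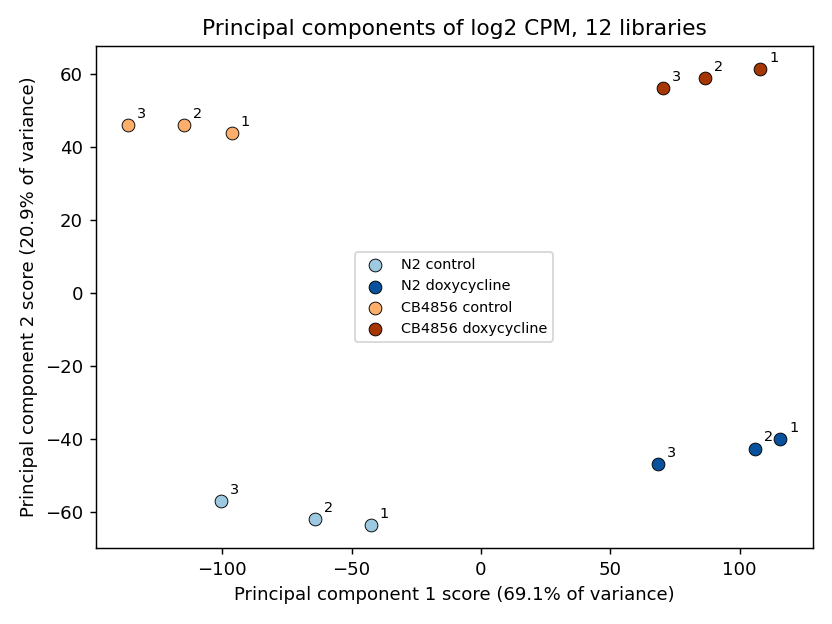
Scores of the 12 libraries on the first 2 principal components of log2 CPM, colored by group, with 3 libraries per group. Component 1 (69.1% of the variance) separates doxycycline from control libraries, and component 2 (20.9%) separates CB4856 from N2.

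In N2, the comparison asked which transcripts doxycycline changed in worms of the reference strain. Oocyte, germline and DNA replication genes fell with the drug, together with all 32 listed subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins. Cuticle collagens, molting genes, sperm genes and innate immune effectors rose. The largest increase by the naming rule was that of parg-2 (WBGene00004052, chromosome IV, 8712408 to 8715132), a poly(ADP-ribose) glycohydrolase gene. It went from 0.142 ± 0.0810 CPM in control to 69.3 ± 12.4 CPM with doxycycline (n = 3 each), a log2 fold change of 8.90 (SE 0.304, edgeR adjusted p = 1.58e-08). In all, 6628 genes were called higher and 5617 lower of 15750 tested, with 4064 and 1404 of them changed over 2-fold.

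Among the other large increases in N2, the collagen gene col-33 (WBGene00000610) had 2 counts in all controls and 1190 with the drug, a ratio of 490 (95% counting interval 135 to 4052). The rest were nspb-11 (7.12), grl-21 (6.77) and idpc-4 (6.65), as log2 fold changes. The gene dct-19 had no counts in N2 control and was at least 7.68-fold higher with doxycycline, a call that limma-voom lost (adjusted p = 0.0585). The largest decreases were those of sepa-1 (-5.80), whose protein links P granule components to autophagy, vet-6 (-5.27), the caveolin gene cav-1 (-3.996), the Skp1-related genes skr-7 (-3.94) and skr-14 (-3.68), and vet-2 (-3.51). For sepa-1 (WBGene00010808, chromosome I, 13298204 to 13300716) normalized counts were 7.41 ± 7.15 CPM in control and 0.129 ± 0.154 CPM with the drug (n = 3 each, edgeR adjusted p = 1.08e-04). Over fits that each left out 1 library the log2 fold change was -7.30 to -4.65 for sepa-1 and -6.01 to -3.97 for vet-6. With the oocyte mean as a covariate, chosen after seeing the data, all 6 of these decreases turned sign and none was called (sepa-1 1.87, vet-6 2.74, cav-1 1.57, skr-7 0.89, skr-14 1.81, vet-2 0.94). That mean alone parts treated from control libraries and so takes up much of the drug contrast. These turns therefore do not tell oocyte content from other effects of the drug.

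Oocyte, germline, replication and yolk genes in N2 fell. All 22 oocyte markers were lower (median log2 fold change -1.53, camera adjusted p = 9.76e-08), as were 31 of 35 germline markers (-0.70, 1.59e-08) and all 26 DNA replication and cell cycle genes (-1.19, 1.28e-08). Each of these lists had adjusted p = 0.532 with an estimated correlation. Examples were the Y-box genes cey-2 (-1.14) and cey-3 (-1.07), the latter at 740 ± 19.1 CPM in control and 353 ± 54.6 CPM with the drug, the meiotic genes htp-1 (-0.70) and cpb-3 (-0.95), the polo kinase gene plk-1 (-1.21) and the replication gene cdc-6 (-1.001). All 6 vitellogenin genes, which encode yolk proteins, were lower (-1.08, 0.0242; adjusted p = 0.532 with an estimated correlation). That list's call was lost at a mean CPM of at least 5. With the oocyte covariate, chosen after seeing the data, the list reversed direction and passed camera. The share of vitellogenins among reads in genes was 5.81 ± 0.394% in N2 control and 3.99 ± 0.854% in N2 doxycycline, and vit-2 fell by 0.65 on the log2 scale. Sperm genes rose instead, with 33 of 35 spermatogenesis markers higher (1.70, 5.44e-05; adjusted p = 0.532 with an estimated correlation), among them spe-6 (1.90) and spe-41 (2.20). Of 28 major sperm protein genes 27 were higher (1.16, 0.00453; adjusted p = 0.687 with an estimated correlation).

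Collagens, molting genes, immune effectors and C-type lectins rose in N2. Of 134 collagens 98 were higher and 20 lower (median 2.49, camera adjusted p = 5.48e-06), with col-150 (3.01) and col-186 (3.04) among them, and of 30 molting genes 27 were higher (2.81, 4.67e-05), with ptr-18 (2.81) and lpr-3 (3.12). Both lists had adjusted p = 0.532 with an estimated correlation. Of 39 immune effectors 30 were higher and 1 lower (2.15, 1.16e-06; adjusted p = 0.192 with an estimated correlation). The pathogen-response gene irg-5 (WBGene00009429, chromosome V, 13737010 to 13738474) went from 9.79 ± 1.40 to 82.7 ± 4.41 CPM (n = 3 each, log2 fold change 3.08, SE 0.113, edgeR adjusted p = 2.78e-08), and irg-4 rose by 2.51. Of 126 C-type lectins, sugar-binding proteins often induced by pathogens, 74 were higher and 12 lower (0.87, 1.40e-04; adjusted p = 0.532 with an estimated correlation), including clec-4 (2.94) and clec-66 (1.59).

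Proteasome, mitochondrial ribosome, mitochondrial translation and autophagy genes in N2 fell. All 32 listed proteasome subunits fell (median -0.64, camera adjusted p = 7.93e-10; adjusted p = 0.532 with an estimated correlation), with rpn-5 (-0.79) and rpt-4 (-0.73) the clearest. Of 69 mitochondrial ribosomal protein genes 51 were lower and none higher (-0.28, 4.77e-07; adjusted p = 0.532 with an estimated correlation), with mrpl-34 (-0.61) and mrps-2 (-0.52) as examples. That list's median was -0.0078 with upper quartile scaling and -0.35 with RLE, and its call was lost among genes of mean CPM of at least 5 (0.135). Of 15 mitochondrial translation factors 10 were lower (-0.40, 0.0191), and of 26 autophagy genes 15 were lower and 5 higher (-0.48, 0.0406). Upper quartile scaling ended both calls (0.149 and 0.0814), as did a mean CPM of at least 5 (0.331 and 0.486), and each list had adjusted p = 0.532 with an estimated correlation. The lists of the mitochondrial unfolded protein response did not pass camera. Of 11 chaperones and proteases 1 was higher and 4 lower (camera adjusted p = 0.484, fry 0.117), and of 12 regulators 3 were higher and 7 lower (median -0.51, camera 0.155), the latter lower by fry (9.31e-04). The chaperone gene hsp-6 rose by 0.30 (adjusted p = 6.43e-04), from 623 ± 11.7 to 767 ± 33.1 CPM, while hsp-60 fell by 0.43 (6.71e-04), a call lost with upper quartile scaling (0.0725). The regulator atfs-1 had -0.081 (adjusted p = 0.196), which turned to 0.20 with upper quartile scaling.

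Muscle, pharynx, neuron and intestine markers in N2 rose. Body muscle had 20 of 21 genes higher (median 0.63, camera adjusted p = 5.50e-04), pharynx 14 of 15 (1.18, 0.00148), neurons 19 of 23 (0.76, 0.00312), neuropeptides 33 of 51 (0.59, 2.28e-04) and intestine 16 of 21 (0.65, 0.00753). Higher and lower were 33 and 8 of 64 glucuronosyltransferases (0.45, 0.0420), 44 and 13 of 89 chemoreceptors (0.55, 0.0390) and 58 and 21 of 117 fbxa F-box genes (0.69, 0.0420). Each of these 8 lists had adjusted p = 0.532 with an estimated correlation. Of all 15750 genes 6628 were higher and 5617 lower, so the higher shares of glucuronosyltransferases, chemoreceptors and fbxa genes were not far above that of all genes. The chemoreceptor call was lost without N2 control replicate 1 (0.0543), as were the glucuronosyltransferase (0.0836) and fbxa (0.0523) calls, and upper quartile scaling ended all 3 (0.0803, 0.0592 and 0.0922). The glucuronosyltransferase call was also lost without N2 control replicate 3 (0.0528) or N2 doxycycline replicate 2 (0.0509), and the autophagy call without N2 control replicate 3 (0.0514).

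Normalization set the balance of these calls. Of the called genes in N2 54.1% were higher with TMM and 65.3% with upper quartile scaling, which moved the median of all genes from 0.19 to 0.47, and a mean CPM of at least 5 moved it to 0.0038. With the oocyte mean as a covariate, chosen after seeing the data, 544 genes were higher and 99 lower. That mean alone parts treated from control libraries, so a loss of calls does not show its cause.

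In CB4856, the same question was asked of the Hawaiian isolate. Its oocyte, germline, replication and proteasome genes fell, and its collagen, sperm and immune genes rose, in the directions seen in N2. The gene parg-2 again had the largest increase by the naming rule, from 0.287 ± 0.0964 to 91.5 ± 17.7 CPM (n = 3 each), a log2 fold change of 8.29 (SE 0.273, edgeR adjusted p = 1.03e-08). The pathogen-response gene irg-5 followed a similar course, from 2.70 ± 0.219 to 145 ± 13.9 CPM (5.74, SE 0.132, 4.85e-10). In all, 7649 genes were called higher and 5603 lower, 5093 and 2517 of them over 2-fold.

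Other large increases in CB4856 were those of nspe-7 (6.24), the channel gene cng-1 (6.22), the glucuronosyltransferase gene ugt-29 (5.55) and oac-20 (5.53). For cng-1 (WBGene00000562, chromosome V, 15025731 to 15031473) normalized counts were 1.05 ± 0.291 CPM in control and 78.7 ± 11.8 CPM with the drug (n = 3 each, edgeR adjusted p = 2.22e-08). The largest decreases were vet-6 (-8.11), cav-1 (-6.43), sepa-1 (-5.75), vet-2 (-5.11), the chitinase gene cht-1 (-4.92) and skr-15 (-4.92). With the oocyte covariate, chosen after seeing the data, those of vet-6, cav-1, sepa-1, vet-2 and skr-15 turned sign. That covariate alone parts treated from control libraries, so the turns do not tell oocyte content from other effects of the drug. The gene vet-6 (WBGene00006902, chromosome I, 13269984 to 13272781) went from 25.8 ± 3.59 to 0.0885 ± 0.0464 CPM (n = 3 each, edgeR adjusted p = 4.82e-06).

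Falling groups in CB4856 were all 22 oocyte genes (median -2.03, camera adjusted p = 1.04e-07; adjusted p = 0.543 with an estimated correlation), among them cey-2 (-1.58) and cey-3 (-1.44). All 26 replication genes (-1.60, 2.14e-09), 32 of 35 germline genes (-0.96, 4.69e-09) and all 32 listed proteasome genes (-0.84, 3.89e-10) were lower. Those 3 lists had adjusted p = 0.512 with an estimated correlation, and their examples were plk-1 (-1.66), pola-1 (-1.22), cpb-3 (-1.35), nos-3 (-1.11), rpn-5 (-1.02) and rpt-4 (-0.88). Of 69 mitochondrial ribosomal protein genes 61 were lower and none higher (-0.43, 7.44e-10; adjusted p = 0.357 with an estimated correlation). For mrpl-34 (-0.97), 43.3 ± 1.44 CPM in control compared with 22.1 ± 0.801 CPM with the drug, and mrpl-18 had -0.94. The list's median was -0.078 with upper quartile scaling and -0.69 with RLE. Mitochondrial translation factors had 11 of 15 lower (-0.46, 0.00876; adjusted p = 0.466 with an estimated correlation) and autophagy 17 of 26 (-0.56, 0.0139; adjusted p = 0.561 with an estimated correlation). A mean CPM of at least 5 ended both calls (0.253 and 0.343), and upper quartile scaling that of the translation factors (0.106).

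Rising groups in CB4856 were 112 of 134 collagens (median 2.22, camera adjusted p = 1.67e-06; adjusted p = 0.558 with an estimated correlation), with col-150 (3.33) and col-186 (3.19). With the oocyte covariate, chosen after seeing the data, the collagen list reversed direction and still passed camera. Sperm genes rose, with 32 of 35 spermatogenesis markers (3.63, 4.36e-06) and 27 of 28 major sperm protein genes (3.52, 8.55e-06) higher. Both had adjusted p = 0.561 with an estimated correlation, and examples were spe-41 (3.15), ssp-16 (3.83), msp-3 (4.04) and msp-77 (3.68). Of 39 immune effectors 32 were higher (1.77, 3.10e-05; adjusted p = 0.357 with an estimated correlation), with irg-4 at 4.54. Of the detoxification lists 2 of 3 passed, with 49 of 64 glucuronosyltransferases (1.03, 1.60e-04) and 25 of 44 glutathione S-transferases (0.82, 0.0180) higher. Both had adjusted p = 0.357 with an estimated correlation, ugt-54 had 2.33, and cytochromes P450 did not pass camera (0.0996). C-type lectins had 88 of 126 higher (1.08, 1.81e-04; adjusted p = 0.404 with an estimated correlation). Chemoreceptors had 51 higher and 10 lower of 89 (0.96, 0.0139) and fbxa genes 72 and 18 of 117 (1.00, 0.0235), each with adjusted p = 0.357 with an estimated correlation. Of all 15750 genes 7649 were higher and 5603 lower. A mean CPM of at least 5 ended both list calls. The chemoreceptor call was also lost with the strand-specific column and without a low-count filter, and the fbxa call with upper quartile scaling. Neuropeptides had 42 of 51 higher (0.79, 1.65e-04), neurons 21 of 23 (0.98, 0.00304) and pharynx 14 of 15 (1.17, 0.00558). Each of these 3 had adjusted p = 0.512 with an estimated correlation. Body muscle had 19 of 21 higher (0.90, 5.70e-04; adjusted p = 0.561 with an estimated correlation) and intestine 19 of 21 (0.70, 0.00910; adjusted p = 0.530 with an estimated correlation). For these tissue lists, as in N2, higher expression within a tissue cannot be told apart from a larger share of it in whole worms.

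Molting genes and vitellogenins passed camera in N2 and not in CB4856. Of 30 molting genes 17 were higher in CB4856 (median 1.21, camera adjusted p = 0.101, fry 0.0163), and of 6 vitellogenins none was called (-0.25, 0.430; 0.091 with upper quartile scaling). The gene vit-2 had -0.13 (adjusted p = 0.430), and vitellogenins held 5.83 ± 0.278% of reads in CB4856 control and 5.99 ± 1.08% with the drug. The chaperone gene hsp-60 fell by 0.76 (adjusted p = 5.87e-06), from 516 ± 5.55 to 305 ± 31.3 CPM. The gene hsp-6 had 0.10 (adjusted p = 0.129), called higher with upper quartile scaling (0.45) and lower with RLE (-0.16), and atfs-1 had -0.023 (0.705), lower with RLE (-0.28) and higher with upper quartile scaling (0.33). The mitochondrial unfolded protein response had 1 of 11 genes higher and 6 lower (camera 0.139), and its regulators 4 of 12 higher and 7 lower (0.218), both lower by fry (8.07e-04 and 1.03e-04). With upper quartile scaling the median of the 11 genes turned from -0.16 to 0.19, and in N2 from -0.039 to 0.24.

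The balance in CB4856 also depended on scaling. Higher genes made up 57.7% of the called genes with TMM, 66.6% with upper quartile scaling and 49.6% with DESeq2, and the median of all genes moved from 0.45 to 0.80 and 0.19, and to 0.053 at a mean CPM of at least 5. With the oocyte mean as a covariate, chosen after seeing the data and by itself parting treated from control libraries, 1757 genes were higher and 817 lower.

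Respiratory chain lists did not pass camera in either strain. Of 12 subunits encoded by mitochondrial DNA 5 were higher in N2 (camera adjusted p = 0.762) and 4 higher and 1 lower in CB4856 (0.717). The transcript ND1 (MtDNA, 1763 to 2635) had 0.21 in N2 (adjusted p = 0.0427) and 0.34 in CB4856 (0.00317). Its N2 call was lost without N2 control replicate 1 (0.0769) or 3 (0.173) or N2 doxycycline replicate 1 (0.182) or 2 (0.0678), and RLE ended both calls (0.126 and 0.363). COX1 had -0.053 in N2 (0.544; 0.22 with upper quartile scaling) and 0.079 in CB4856 (0.353; -0.18 with RLE). Nuclear subunits of complex I were 1 higher and 6 lower of 32 in N2 (0.142) and 2 and 5 in CB4856 (0.603), and those of complexes II to IV 6 and 2 of 22 (0.714) and 7 and 2 (0.433). For ATP synthase they were 3 and 4 of 15 (0.800) and 4 and 4 (0.840), and for mitochondrial import 1 and 8 of 12 (0.136) and 3 and 8 (0.109). Fry called mitochondrial import lower in both strains (0.00137 and 1.03e-04) and complexes II to IV higher in CB4856 (0.0164), with medians that turned sign with upper quartile scaling for import (0.067 and 0.090) and with RLE for complexes II to IV (-0.14).

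Other fixed lists did not pass camera with doxycycline, given as genes higher and lower in N2 and then in CB4856 with the camera adjusted p. Metabolic lists were the tricarboxylic acid cycle with 4 and 4 of 20 (0.810), then 7 and 4 (0.927), and glycolysis with 3 and 9 of 19 (0.160), then 7 and 9 (0.616). Fatty acid metabolism had 10 and 13 of 35 (0.751), then 20 and 6 (0.408), and the propionate shunt 0 and 4 of 5 (0.0515), then 0 and 4 (0.126). One-carbon and serine metabolism had 4 and 6 of 17 (0.254), then 3 and 8 (0.343). Stress lists were cytosolic heat shock with 4 and 5 of 14 (0.728), then 8 and 5 (0.927), the endoplasmic reticulum response with 4 and 6 of 18 (0.630), then 5 and 7 (0.433), and oxidative stress with 5 and 6 of 21 (0.762), then 8 and 5 (0.927). Hypoxia had 4 and 4 of 12 (0.859), then 5 and 3 (0.927), cytochromes P450 had 24 and 13 of 59 (0.431), then 33 and 9 (0.0996), and glutathione S-transferases in N2 had 18 and 4 of 44 (0.127). The remaining lists were pals genes with 12 and 1 of 22 (0.0508), then 13 and 0 (0.0595), and cytosolic ribosome with 3 and 6 of 81 (0.160), then 3 and 3 (0.717). Histones had 4 and 13 of 29 (0.0752), then 9 and 17 (0.0918), hypodermis 11 and 2 of 16 (0.127), then 9 and 3 (0.517), and MATH and BTB domain genes 19 and 19 of 58 (0.619), then 22 and 17 (0.808). Of the lists in this paragraph fry called higher in N2 pals (2.65e-05), glutathione S-transferases (4.49e-05), cytochromes P450 (8.35e-05) and hypodermis (5.53e-04), and lower the propionate shunt (0.00157), one-carbon metabolism (0.00269), glycolysis (0.00692) and histones (0.00747), with medians that upper quartile scaling turned for one-carbon metabolism (0.011) and glycolysis (0.23). In CB4856 fry called higher cytochromes P450 (3.59e-06), pals (1.27e-05), fatty acid metabolism (5.74e-04), hypoxia (0.0141), hypodermis (0.0237) and oxidative stress (0.0444), and lower the propionate shunt (0.00335), histones (0.00587) and one-carbon metabolism (0.0107), with medians that upper quartile scaling turned for one-carbon metabolism (0.14) and hypoxia (0.21) and RLE brought to 0 for oxidative stress. Median, mean and camera direction differed in sign in N2 for ATP synthase, fatty acid metabolism, heat shock, hypoxia, MATH and BTB domain genes, oxidative stress, the tricarboxylic acid cycle and the endoplasmic reticulum response. In CB4856 they differed for ATP synthase, complex I, cytosolic ribosome, glycolysis, heat shock, hypoxia, MATH and BTB domain genes, one-carbon metabolism and the tricarboxylic acid cycle.

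**Figure D2:**
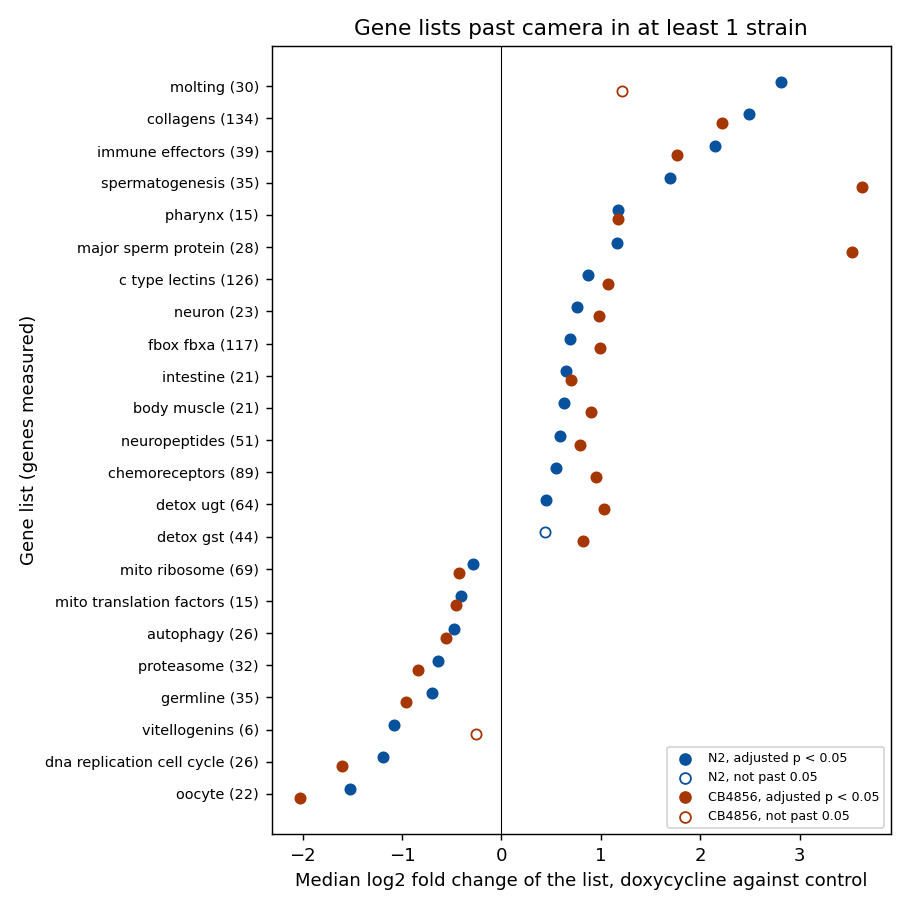
Median log2 fold change with doxycycline of each gene list past camera in at least 1 strain, for N2 and CB4856, with the number of genes measured after each name. Filled points passed an adjusted p of 0.05 with the preset correlation and open points did not, and no list passed with an estimated correlation.

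The comparison of the responses asked how far the strains shared them. Both strains raised 6128 genes in common, where 3219 were expected from independent calls, and lowered 5161 in common, where 1998 were expected, while 93 were called in opposite directions. Genes such as parg-2, irg-5, col-150 and spe-41 rose in both, and cey-2, plk-1, rpn-5, sepa-1 and vet-6 fell in both. Across the 15750 genes the log2 fold changes correlated with Pearson r = 0.865 and Spearman rho = 0.920, with 91.6% of the same sign. The spread of the changes was 1.17 times as large in CB4856. The strains' comparisons shared no libraries, and genes are not independent replicates. With the oocyte covariate r was 0.738, and without a low-count filter 0.659.

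**Figure D3:**
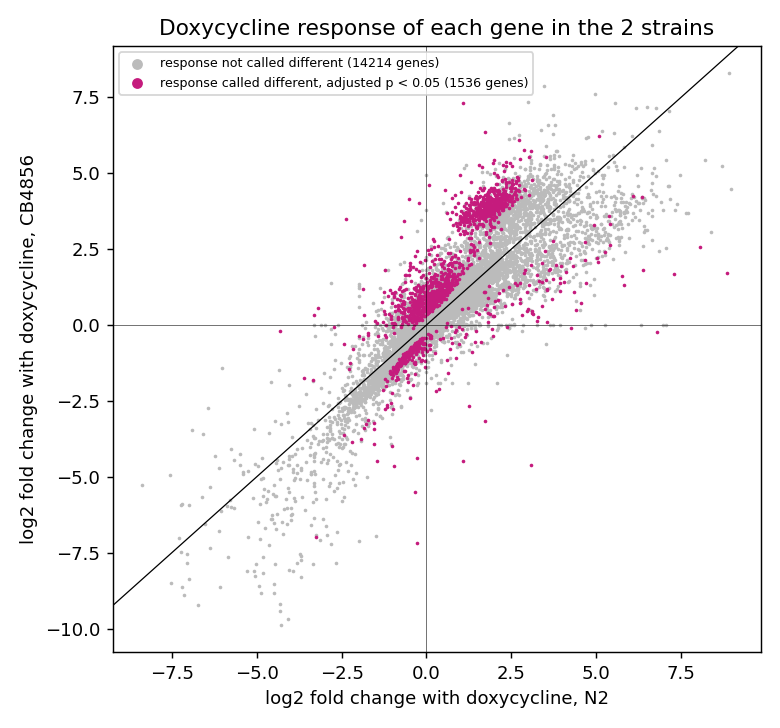
Log2 fold change with doxycycline of each of 15750 genes in N2 (horizontal) and CB4856 (vertical), with the line of equal change. Colored points are the 1536 genes whose response differed between the strains by the interaction test.

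The interaction asked which genes responded differently in the strains, taking a positive value as a more positive response in CB4856. By camera the sperm lists were shifted toward a larger rise in CB4856 and the molting list toward a larger rise in N2, with 20 of 35 spermatogenesis and 8 of 30 molting genes called. Both shifts were lost by fry (0.120 each) and had adjusted p = 0.786 with an estimated correlation. The major sperm protein gene msp-3 (WBGene00003424, chromosome II, 4785898 to 4786281) went from 21.8 ± 8.81 to 53.8 ± 6.07 CPM in N2 and from 3.70 ± 1.93 to 60.9 ± 3.18 CPM in CB4856 (n = 3 per group), an interaction of 2.728 (SE 0.464, edgeR adjusted p = 0.00899). The molting gene lpr-3 (WBGene00012261, chromosome X, 11057401 to 11059793) went from 1.47 ± 0.565 to 12.64 ± 4.5005 CPM in N2 and from 5.55 ± 1.35 to 7.26 ± 2.13 CPM in CB4856 (-2.734, SE 0.484, adjusted p = 0.0105). In all, 1145 genes had a more positive and 391 a more negative response in CB4856, 752 and 141 of them by over 2-fold. Of the 1536 genes, 886 were raised more in CB4856 and 88 more in N2, 259 were lowered more in CB4856 and 21 more in N2, and 282 had changes of opposite sign. Of the 2733 genes called for doxycycline in 1 strain alone, 405 had an interaction call.

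By the naming rule, the most positive interactions were msp-64 (3.93), the dehydrogenase gene dhs-26 (3.75), the phosphatase gene ptp-5.3 (3.59), sosi-1 (3.44), msp-10 (3.096) and phyh-1 (2.88). The gene dhs-26 (WBGene00000989, chromosome X, 3360722 to 3362493) went from 41.6 ± 15.8 to 4.56 ± 0.574 CPM in N2 and from 0.989 ± 0.355 to 1.47 ± 0.375 CPM in CB4856 (SE 0.475, edgeR adjusted p = 0.00230). For sosi-1 the values were 2.53 ± 0.398 and 4.53 ± 1.39 CPM in N2, and 0.797 ± 0.191 and 15.6 ± 1.78 CPM in CB4856 (adjusted p = 0.00117). The most negative were the acyl-CoA dehydrogenase gene acdh-2 (-4.09), the collagen gene dpy-14 (-3.46), the cuticlin gene cut-2 (-2.85), dao-2 (-2.77), lpr-3 (-2.734) and mlt-11 (-2.47). The gene acdh-2 (WBGene00015894, chromosome II, 5544778 to 5547492) held 19.03 ± 4.27 and 15.8 ± 1.71 CPM in N2 but went from 9.15 ± 4.02 to 0.438 ± 0.170 CPM in CB4856 (SE 0.466, edgeR adjusted p = 0.00142). In limma-voom msp-64 (0.161), dpy-14 (0.127) and cut-2 (0.129) were not called.

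The sperm lists carried the largest group differences, with 23 of 28 major sperm protein genes (median 2.43, camera adjusted p = 4.22e-10) and 20 of 35 spermatogenesis genes (1.91, 2.47e-07) more positive in CB4856, among them ssq-3 (2.77) and spe-12 (2.81). Both had adjusted p = 0.786 with an estimated correlation, and fry gave 0.0655 and 0.120. The mean of the major sperm protein list was lowest in untreated CB4856 (-0.015 to 1.39, log2 CPM, against 3.04 to 4.497 in untreated N2). With the drug ssq-3 reached 23.3 ± 1.28 CPM in CB4856 and 24.4 ± 0.202 CPM in N2. Glucuronosyltransferases had 13 of 64 genes more positive (0.47, 1.88e-06), with ugt-28 (2.42) and ugt-41 (1.55), and glutathione S-transferases 4 of 44 (0.30, 0.0119), with gst-4 (0.84) and gst-28 (0.78). These lists each had adjusted p = 0.531 with an estimated correlation. Fatty acid metabolism had 7 of 35 more positive and 1 more negative (0.39, 0.0136), including the acyl-CoA oxidase gene acox-1.1 (0.65) and the lipase gene lipl-3 (2.37), and cytochromes P450 3 and 1 of 59 (0.35, 0.0344), with cyp-37A1 (0.59) and cyp-35A2 (0.74). Each of the 2 had adjusted p = 0.786 with an estimated correlation. Vitellogenins had 1 of 6 more positive (0.76, 0.0136; adjusted p = 0.786 with an estimated correlation), namely vit-3 (1.05), and 5 of 6 when adjusted over the list alone. The vitellogenin call was lost without N2 control replicate 3 (0.0674) or CB4856 control replicate 1 (0.0560). Body muscle, with unc-27 (0.33), had 1 of 21 more positive (0.27, 0.0144) and neurons, with egl-21 (0.37), 1 of 23 (0.27, 0.0395). The 2 lists had adjusted p = 0.786 with an estimated correlation. The body muscle call was lost without N2 control replicate 1 (0.0814), N2 doxycycline replicate 3 (0.0870) or CB4856 control replicate 3 (0.0616), and that of cytochromes P450 without N2 control replicate 3 (0.0748) or CB4856 control replicate 1 (0.124). RLE ended the body muscle (0.134) and neuron (0.105) calls, with medians of 0.078 and 0.088, and fry gave 0.183 and 0.120, and 0.120 for vitellogenins. Neurons were not called without N2 control replicate 1 (0.0573) or 3 (0.0748), N2 doxycycline replicate 3 (0.153), CB4856 control replicate 1 (0.0588) or 3 (0.0979), or CB4856 doxycycline replicate 1 (0.0924).

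More negative in CB4856 were 8 of 30 molting genes, with 1 more positive (median -1.58, camera adjusted p = 6.42e-06), including noah-1 (-1.65), and 3 of 69 mitochondrial ribosomal protein genes (-0.17, 2.67e-06), including mrpl-34 (-0.36) and mrpl-48 (-0.35). These lists each had adjusted p = 0.786 with an estimated correlation, and fry gave 0.120 for molting. Replication genes (-0.38, 2.68e-05), proteasome genes (-0.21, 1.37e-04) and oocyte genes (-0.44, 0.00821) passed camera with no member called, and germline genes (-0.26, 1.93e-04) with 1, nos-3 (-0.46). Each had adjusted p = 0.786 with an estimated correlation, and fry gave 0.158 to 0.379. The oocyte call was lost without N2 doxycycline replicate 3 (0.172) or CB4856 doxycycline replicate 1 (0.0836). The chaperone genes hsp-6 (-0.20, adjusted p = 0.146) and hsp-60 (-0.33, 0.102) were not called, although RLE called both (0.0230 and 0.0250) and hsp-60 was called without N2 doxycycline replicate 1 (0.0495) or CB4856 doxycycline replicate 3 (0.0427). Not called either were atfs-1 (0.058, 0.637), vit-2 (0.52, 0.142; 0.0400 without N2 doxycycline replicate 3), ND1 (0.13, 0.489) and COX1 (0.13, 0.435). With RLE atfs-1 (-0.14), ND1 (-0.061) and COX1 (-0.061) turned sign.

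The count of interaction genes rested on single libraries, on scaling and on the oocyte covariate. It also moved with replicate number as a block, given with the other settings below. Without the replicates 3 of N2 control and N2 doxycycline, a setting chosen after seeing the data, 1774 genes were more positive and 696 more negative. Left out in turn, N2 control replicates 1, 2 and 3 gave 410, 291 and 1720 genes with the more positive response, N2 doxycycline replicates 1 and 2 gave 683 and 430, CB4856 control replicates 2 and 3 gave 289 and 462, and CB4856 doxycycline replicate 2 gave 344. Genes with the more negative response numbered 120 and 78 without N2 control replicates 1 and 2, 241 and 131 without N2 doxycycline replicates 1 and 2, 77 and 133 without CB4856 control replicates 2 and 3, and 78 without CB4856 doxycycline replicate 2. The more positive share was 74.5% with TMM, 81.5% with upper quartile scaling, 62.5% without a filter, 32.5% with RLE, 28.7% with DESeq2 and 56.96% with the oocyte covariate (1788 genes more positive and 1351 more negative), and RLE moved the median of all genes from -0.015 to -0.21. Among the named interaction genes, dhs-26, ptp-5.3, sosi-1, msp-10, phyh-1, acdh-2, dao-2, lpr-3, msp-3, ssq-3, spe-12, ugt-28, ugt-41, noah-1, gst-4, gst-28 and acox-1.1 stayed called without any single library. The calls of msp-64, dpy-14, cut-2, mlt-11, mrpl-34, mrpl-48, nos-3, lipl-3, vit-3, unc-27, cyp-37A1, cyp-35A2 and egl-21 were each lost without at least 1 library. For lipl-3 that was N2 control replicate 2 (adjusted p = 0.0743), and for cyp-37A1 it was CB4856 control replicate 2 (0.0502). Calls were lost in 9 of the 12 such fits for dpy-14 (0.0529 to 0.112), cut-2 (0.0520 to 0.0878), vit-3 (0.0589 to 0.0911) and unc-27 (0.0531 to 0.0971), in 11 for mrpl-34 (0.0529 to 0.120), 10 for mrpl-48 (0.0575 to 0.121), 7 for egl-21 (0.0522 to 0.0761) and 5 for nos-3 (0.0552 to 0.0695).

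**Figure D4:**
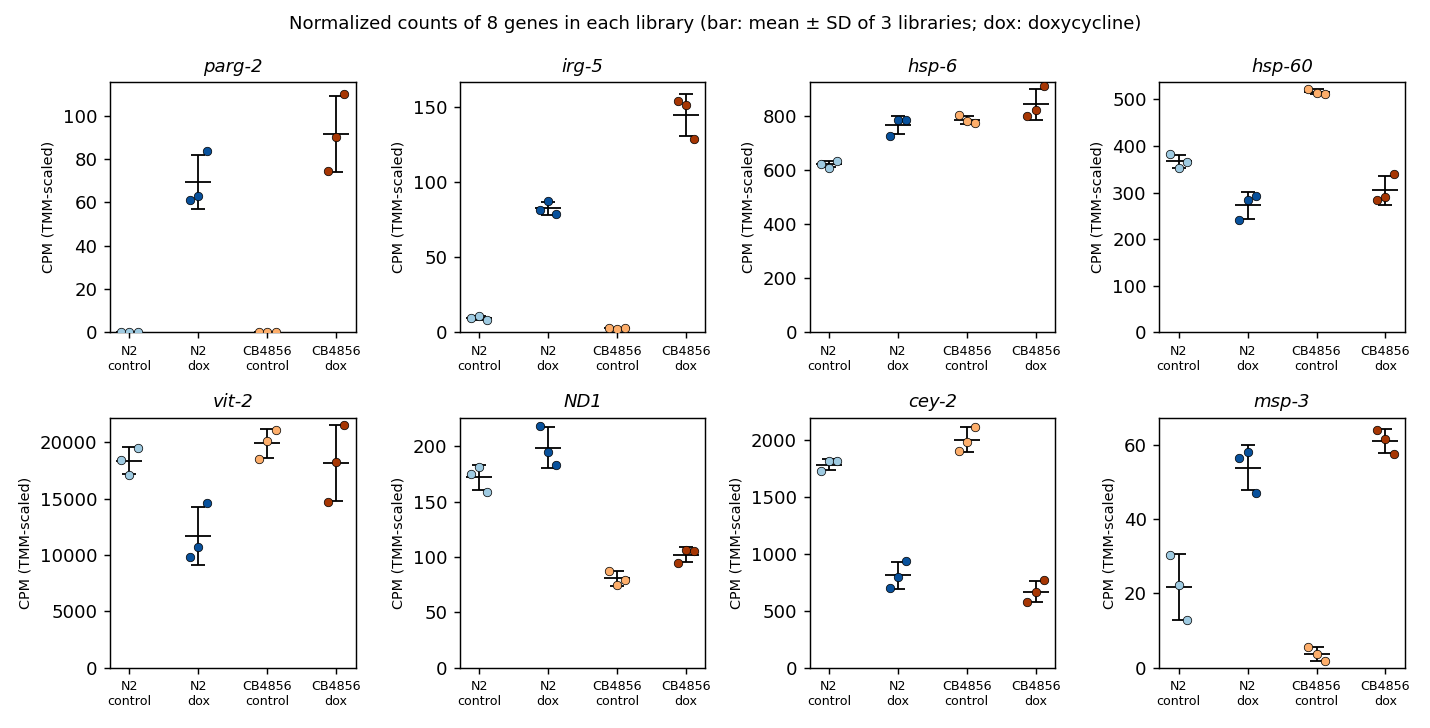
Normalized counts (CPM) of parg-2, irg-5, hsp-6, hsp-60, vit-2, ND1, cey-2 and msp-3 in each library, with the mean and SD of 3 libraries per group. Doxycycline libraries lie above control for parg-2 and irg-5 and below it for cey-2 in both strains, while msp-3 is lowest in CB4856 control.

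Without doxycycline, the comparison of CB4856 with N2 asked how the isolates differ at baseline. Sperm genes and ribosomal protein genes were lower in CB4856, and single members of fast-evolving families were undetected there. Reads of CB4856 were counted against the N2 reference, so low counts of a gene can come from missing or diverged sequence as well as from lower expression. The F-box gene fbxa-206 (WBGene00013610, chromosome V, 16917201 to 16918478) had 28.4 ± 2.33 CPM in N2 and no counts in CB4856 control (n = 3 each), at least 198-fold lower. Other genes without counts in CB4856 control were bath-28 (at least 144-fold lower), clec-10 (at least 140-fold), msp-19 (at least 131-fold), pud-4 (at least 105-fold) and msp-53 (at least 74.2-fold). In all, 1607 genes were higher and 2497 lower in CB4856, 684 and 1452 of them over 2-fold. The largest increases were irg-6 (5.49), clec-71 (4.73), cyp-37B1 (4.11), math-38 (3.65) and ppt-1 (3.55), a palmitoyl-protein thioesterase gene. For irg-6 (WBGene00007864, chromosome IV, 12912722 to 12914969) levels were 0.179 ± 0.0767 CPM in N2 and 8.05 ± 0.548 CPM in CB4856 (n = 3 each, SE 0.212, edgeR adjusted p = 1.32e-08). The gene dct-19 had no counts in N2 control and was at least 12.4-fold higher in CB4856, a call lost in limma-voom (0.0773).

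Sperm and ribosome lists were lower in untreated CB4856. Of 28 major sperm protein genes 27 were lower (median -2.54, camera adjusted p = 2.94e-15), with msp-64 (-9.14) and msp-33 (-5.86), of 35 spermatogenesis genes 24 (-1.79, 6.11e-08), with ssq-3 (-2.84) and ssq-4 (-2.68), and of 81 cytosolic ribosomal protein genes 59 (-0.25, 6.00e-11), with rpl-2 (-0.56) and rpl-9 (-0.46). These lists had adjusted p = 0.830 with an estimated correlation. Transcripts of mitochondrial DNA were lower for 6 of 12 genes (-0.48, 0.00263), with ND1 (-1.09) at 172 ± 11.5 CPM in N2 and 80.7 ± 6.45 CPM in CB4856, and COX1 (-0.57). Complex I had 15 of 32 genes lower (-0.18, 1.34e-04), with ndab-1 (-0.64) and lpd-5 (-0.29). Both lists had adjusted p = 0.830 with an estimated correlation. Complexes II to IV had 5 of 22 lower (-0.14, 0.0477; adjusted p = 0.897 with an estimated correlation), with R07E4.3 (-0.49) and cox-5A (-0.23), and RLE ended the calls of the list (0.298) and of cox-5A (0.0917). That list's call was also lost without N2 control replicate 1 (0.0776) or 2 (0.123) or CB4856 control replicate 1 (0.116), 2 (0.0563) or 3 (0.0524), and that of cox-5A without N2 control replicate 2 (0.0574). MATH and BTB domain genes had 27 of 58 lower and 12 higher (-0.50, 0.00172; adjusted p = 0.830 with an estimated correlation), with bath-5 (-5.08) and bath-1 (-5.74).

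Molting, replication and oocyte lists passed camera on the higher side in untreated CB4856, and fry lost all 3 (0.0577, 0.164 and 0.317). Of 30 molting genes 12 were higher and 1 lower (median 1.095, camera adjusted p = 3.98e-04; adjusted p = 0.830 with an estimated correlation), with noah-1 (1.18) and the fibrillin-like gene fbn-1 (2.22). Replication genes had 5 of 26 higher (0.27, 0.00181), with mcm-4 (0.74) and cya-1 (0.38), and oocyte genes 1 of 22 (0.30, 0.0354), lin-41 (0.55). Each of the 2 had adjusted p = 0.897 with an estimated correlation. The oocyte list was not called with RLE (0.0559), nor without N2 control replicate 1 (0.0708) or 2 (0.0669) or CB4856 control replicate 2 (0.0521) or 3 (0.101). The call of cya-1 was lost without N2 control replicate 1 (0.0623) or 2 (0.0678) or CB4856 control replicate 2 (0.0796) or 3 (0.0739), and that of lin-41 without N2 control replicate 1 (0.120) or 2 (0.139) or CB4856 control replicate 1 (0.0702), 2 (0.115) or 3 (0.0931). The chaperone genes hsp-6 (0.34, adjusted p = 0.00174) and hsp-60 (0.49, 0.00162) were higher in CB4856, whereas atfs-1 (0.13, 0.0960) and vit-2 (0.12, 0.615) were not called. Higher genes made up 39.2% of the called genes with TMM, 50.99% with RLE, 52.1% with DESeq2 and 50.9% without a low-count filter. Their count was 1035 without N2 control replicate 1, 891 without N2 control replicate 2, and 960 and 1019 without CB4856 control replicates 2 and 3.

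Of the genes known to carry functional variants between these isolates, 5 of 8 were measured, and the list did not pass camera in N2 (adjusted p = 0.484), in CB4856 (0.840) or between untreated strains (0.233). The sperm-delivered toxin gene peel-1, known to be absent from the CB4856 genome, had 1.41 ± 0.799 CPM in N2 control, 7.55 ± 0.833 CPM in N2 doxycycline (log2 fold change 2.45, adjusted p = 5.98e-04) and no counts in CB4856, at least 9.80-fold lower without the drug. No response of peel-1 could be measured in CB4856, where it is listed at 0. The Argonaute gene ppw-1 was lower in CB4856 (-1.04, adjusted p = 1.33e-06) and had -0.22 with the drug in N2 (0.0118) and -0.42 in CB4856 (1.81e-04). Its N2 call was lost without N2 control replicate 1 (0.0553), and upper quartile scaling ended both drug calls (0.504 and 0.376). The receptor gene tyra-3 rose with the drug in N2 (1.00, 7.01e-04) and CB4856 (0.77, 0.00294; 0.0705 with DESeq2), and did not pass between strains (0.19, 0.539) or in the interaction (-0.22, 0.609). For scb-1 the values were 0.14 in N2 (0.207), 0.28 in CB4856 (0.0165), 0.14 for the interaction (0.492) and -0.15 between strains (0.289). RLE ended the CB4856 call of scb-1 (0.844), as did leaving out CB4856 control replicate 1 (0.0684) or CB4856 doxycycline replicate 2 (0.0672). The globin gene glb-5 had 2 counts in N2 control and 8 with the drug, a ratio of 3.30 (95% counting interval 0.658 to 31.9; edgeR adjusted p = 0.189, and 0.0377 without N2 doxycycline replicate 2), and 12 counts in CB4856 control, a ratio of 5.52 to N2 (1.23 to 50.8; not called, edgeR adjusted p = 0.107). In CB4856 glb-5 had 1.62 with the drug (adjusted p = 0.0159), a call lost without CB4856 control replicate 2 (0.0691) or CB4856 doxycycline replicate 2 (0.0589), and its interaction was 0.050 (0.986). The interaction of ppw-1 was -0.20 (0.217).

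With doxycycline, the strains were compared again. The mitochondrial ribosome list was lower in treated CB4856, with 33 of 69 genes lower (median -0.24, camera adjusted p = 2.18e-13; adjusted p = 0.501 with an estimated correlation), as was the proteasome, with 18 of 32 (-0.25, 2.09e-07; adjusted p = 0.798 with an estimated correlation). Cytochromes P450 were higher, with 19 of 59 genes higher and 5 lower (0.45, 6.26e-06; adjusted p = 0.139 with an estimated correlation), as were C-type lectins, with 51 and 14 of 126 (0.32, 7.14e-05; adjusted p = 0.506 with an estimated correlation). Major sperm proteins had 4 of 28 lower (-0.13, 0.0592) and spermatogenesis 1 higher and 1 lower of 35 (-0.014, 0.937). Of the 46 lists 11 passed camera, 10 of them also passed fry, and none passed with an estimated correlation. The camera calls of these lists were not compared under the other alternative settings. In all, 1501 genes were higher and 1457 lower in treated CB4856, 703 and 553 of them over 2-fold. Higher genes made up 50.7% of the called genes with TMM, 60.6% with upper quartile scaling, 31.6% with RLE and 29.1% with DESeq2, and RLE moved the median of all genes from -0.024 to -0.13. Without CB4856 doxycycline replicate 2 the lower genes numbered 958.

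Unmapped reads were 4.29 ± 0.0593% in N2 control, 4.96 ± 0.190% in N2 doxycycline, 4.42 ± 0.135% in CB4856 control and 5.63 ± 0.316% in CB4856 doxycycline (n = 3 each). Multimapped reads were 5.57 ± 0.111%, 5.86 ± 0.121%, 4.64 ± 0.0764% and 6.31 ± 0.108% in the same order. Reads of mitochondrial DNA made up 0.655 ± 0.0444%, 0.793 ± 0.0644%, 0.481 ± 0.0459% and 0.619 ± 0.0319% of reads in genes. Differences in these shares were not tested.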

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

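The tests of scaling and of sequence missing from CB4856, and the percentiles on further axes, were chosen after the result was seen. The tests of stage were written before their results.

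Oocyte and germline genes fell and sperm genes rose with doxycycline in both strains, while the same markers differed among replicates of a group. Scaling between libraries was argued against, since at least 95.3% of the oocyte, germline and spermatogenesis genes called in both strains kept both calls under each of 5 other scalings. An earlier stage at harvest of treated worms stayed open and was consistent with r = 0.411 between the N2 changes and the main axis among CB4856 control libraries, and r = 0.683 between the CB4856 changes and the axis among N2 control libraries. Those libraries are not in the comparison they were set against, and the axes among the other strain's treated libraries gave 0.617 and 0.557. Each axis here and below was oriented so that oocyte genes fall, as they did with the drug. That choice largely set the sign of r, and only its size bears on stage. Vitellogenins, at percentiles 0 to 4.29 on the 4 axes, were all lower in N2 (median -1.08) and not called in CB4856 (-0.25), and slower growth caused by the drug was not tested apart from other effects.

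Genes over 8-fold apart between the strains in both conditions lay mostly on the lower side in CB4856, 211 against 111 with the sperm lists left out. Of all tested genes, 97 had no counts in any CB4856 library and 15 none in any N2 library. Over these genes the strain difference without doxycycline had r = -0.0320 with the axis among N2 doxycycline libraries, so they did not follow that axis. Asking for a gap over 8-fold in both conditions, with the sperm lists left out, can remove stage-dependent genes before the test. It therefore does not decide on a stage difference between the strains. Sequence that CB4856 lacks, or carries in a form that maps poorly to the N2 reference, and lower expression cannot be told apart, since the ratio of 1.90 fell between the bounds set for the test and no CB4856 genome was used here. Outside the sperm lists the classes with most of these genes were fbxa (10 of 117), bath (9 of 34) and math (5 of 24).

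Mitochondrial ribosomal protein genes were lower with doxycycline in both strains, while mitochondrial DNA transcripts did not pass as a list, and their median in CB4856 turned from 0.12 to -0.14 with RLE. For the ribosomal proteins the test of the stage axis did not decide. On the axis among CB4856 control libraries their median lay at percentile 99.93 of random lists matched on expression. The other axes gave 88.5 to 99.9, so these genes lay high among genes of like expression. Their fall with the drug was measured against all genes and was not ranked against such lists. For mitochondrial DNA the stage axis stayed open, at percentile 99.96 among CB4856 control libraries, although the axis among CB4856 doxycycline libraries gave 32.9. Scaling stayed open for calls of single ribosomal protein genes. Upper quartile scaling, which moves genes upward, kept 23.5% (12 of 51) in both strains. The other 4 lower or barely move genes, so their 51 of 51 is no test. Doxycycline also blocks translation in mitochondria, and whether that changed these transcripts was not tested apart from stage and scaling.

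Lists whose response differed between the strains by the interaction test were major sperm proteins (camera adjusted p = 4.22e-10), spermatogenesis (2.47e-07), glucuronosyltransferases (1.88e-06), mitochondrial ribosome (2.67e-06), molting (6.42e-06), replication (2.68e-05), proteasome (1.37e-04) and germline (1.93e-04). Further lists were oocytes (0.00821), glutathione S-transferases (0.0119), fatty acid metabolism (0.0136), vitellogenins (0.0136), body muscle (0.0144), cytochromes P450 (0.0344) and neurons (0.0395). None passed with an estimated correlation (0.531 to 0.786).

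Genes with a more positive response in CB4856 by the same test, as log2 differences, were msp-64 (3.93), dhs-26 (3.75), ptp-5.3 (3.59), sosi-1 (3.44), msp-10 (3.096), phyh-1 (2.88), spe-12 (2.81), ssq-3 (2.77), msp-3 (2.728), ugt-28 (2.42), lipl-3 (2.37), ugt-41 (1.55), vit-3 (1.05), gst-4 (0.84), gst-28 (0.78), cyp-35A2 (0.74), acox-1.1 (0.65), cyp-37A1 (0.59), egl-21 (0.37) and unc-27 (0.33). Genes with a more negative response were acdh-2 (-4.09), dpy-14 (-3.46), cut-2 (-2.85), dao-2 (-2.77), lpr-3 (-2.734), mlt-11 (-2.47), noah-1 (-1.65), nos-3 (-0.46), mrpl-34 (-0.36) and mrpl-48 (-0.35).

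Among these genes some calls were lost without a single library: msp-64 without CB4856 control replicate 2 (adjusted p = 0.0658) or 3 (0.0534), mlt-11 without N2 control replicate 2 (0.0639), N2 doxycycline replicate 2 (0.0507) or CB4856 doxycycline replicate 2 (0.0555), and cyp-35A2 without N2 control replicate 2 (0.0565) or CB4856 control replicate 2 (0.0502). For dpy-14, cut-2, mrpl-34, mrpl-48, nos-3, vit-3, unc-27 and egl-21 between 5 and 11 of the 12 libraries ended the call when left out.

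Reads that mapped nowhere were a larger share with doxycycline, 4.96% in N2 and 5.63% in CB4856, than in the controls (4.29% and 4.42%). What these reads are was not examined, since reads themselves were not analysed here.

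Other splits of the libraries were counted for each comparison. For doxycycline in N2, 1 of 10 splits gave as many called genes (12245, highest other 0), and for doxycycline in CB4856 1 of 10 (13252, highest other 0), which are too few splits for a share under 0.05. The same holds for the strains without doxycycline, 1 of 10 (4104, highest other 0), and with it, 1 of 10 (2958, highest other 1183). For the interaction 3 of 100 drawn splits, the real one included, called at least 1536 genes, a count that depends on the draw. The highest, 4481, kept all 6 controls in place and exchanged the strains of all 6 treated libraries, which adds the strain difference to the contrast.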

How the results depend on the processing

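In all, 244 results (13 counts, 68 list tests and 163 gene values) were set against those of 17 alternative settings that apply to them, and against fits that each left out 1 of the 12 libraries. DESeq2 and limma-voom were not run for lists, fry and the estimated correlation apply to lists alone, the stricter thresholds to counts alone, and the fit of only the compared groups to single contrasts. The oocyte covariate and the fit without N2 replicates 3 were chosen after the result was seen. With normalization without the stage-dependent lists or without mitochondrial DNA, all counts stayed within 1.5 times the main count and no list or named gene changed its call or direction. Limma-voom kept all 13 counts within 1.5 times, and 5 gene calls were lost. Values below are counts that moved by over 1.5 times, lists that lost their call or turned, and genes that turned direction. Gene calls lost without a turn numbered 24 with the oocyte covariate, 8 with RLE, 8 with DESeq2, 7 without a low-count filter, 4 with upper quartile scaling, 4 with the strand-specific column, 2 with only the compared groups, 1 at a mean CPM of at least 5 and 1 without N2 replicates 3. Lists are given by adjusted p and genes by log2 fold change, and where no cause is named the cause was not tested. Depth limits genes near the floor of 3 counts per library, such as glb-5.

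A mean CPM of at least 5 tested fewer genes and left 4190 higher with doxycycline in N2, 4587 in CB4856, 1003 higher in untreated CB4856, 918 higher in treated CB4856 and 4016 higher in both strains. Lists no longer past the threshold in N2 were autophagy and fbxa (0.486), chemoreceptors and mitochondrial ribosome (0.135), mitochondrial translation (0.331) and vitellogenins (0.0678). In CB4856 they were autophagy and fbxa (0.343), chemoreceptors (0.0706) and mitochondrial translation (0.253). Signs turned for atfs-1 (0.13, called) and COX1 (0.16) in N2, and for atfs-1 (0.23, called) and vit-2 (0.12) in CB4856.

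An absolute log2 fold change over 1, a narrower call by construction, left 4064 higher and 1404 lower genes in N2, 5093 and 2517 in CB4856, 752 and 141 for the interaction, 684 and 1452 between untreated strains, 703 and 553 between treated strains, and 3548 and 1252 in both strains. An adjusted p under 0.01, also narrower, left 132 and 46 for the interaction, 752 and 1461 between untreated strains and 888 and 843 between treated strains.

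With the oocyte score as a covariate, which alone parts treated from control libraries and so takes up much of the drug contrast, 544 genes were higher and 99 lower in N2, 1757 and 817 in CB4856, and 446 and 86 in both strains. The interaction had 1788 and 1351, and treated strains 2406 and 2978, and the responses correlated at 0.738. Lists lost in N2 were autophagy (0.801), body muscle (0.297), chemoreceptors, fbxa, neuropeptides and pharynx (0.186), collagens (0.649), glucuronosyltransferases and major sperm proteins (0.887), replication (0.0524), intestine (0.0824), mitochondrial translation (0.138), molting (0.959), neurons (0.366), oocytes (0.727) and spermatogenesis (0.0586), and vitellogenins reversed (7.26e-04). Lists lost in CB4856 were autophagy (0.651), body muscle (0.0924), chemoreceptors, fbxa, mitochondrial translation and neuropeptides (0.115), intestine (0.337), neurons (0.141), oocytes (0.536) and pharynx (0.565), and collagens reversed (0.0402). For the interaction they were body muscle (0.166), neurons (0.240) and oocytes (0.488), and between untreated strains oocytes (0.648). Signs turned in N2 for sepa-1 (1.87), vet-6 (2.74), cav-1 (1.57), skr-7 (0.89), skr-14 (1.81), vet-2 (0.94), vit-2 (0.56), hsp-60 (0.035), ND1 (-0.0059) and scb-1 (-0.045). They turned in CB4856 for vet-6 (2.39), cav-1 (0.72), sepa-1 (4.30), vet-2 (0.52), skr-15 (0.65), atfs-1 (0.056) and vit-2 (1.38, called), for the interaction for glb-5 (-0.043) and between untreated strains for vit-2 (-0.11).

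RLE gave 1930 genes with the more negative response in CB4856 and 2422 lower in treated CB4856. It lost body muscle (0.134) and neurons (0.105) for the interaction, and complexes II to IV (0.298) and oocytes (0.0559) between untreated strains. Signs turned in CB4856 for hsp-6 (-0.16, called) and COX1 (-0.18, called), and for the interaction for atfs-1 (-0.14), ND1 (-0.061), COX1 (-0.061), scb-1 (-0.048) and glb-5 (-0.15). DESeq2 gave 2999 and 2680 for the same counts, with turned signs for hsp-6 (-0.16, called) and COX1 (-0.18, called) in CB4856, and atfs-1 (-0.14), ND1 (-0.061), COX1 (-0.061) and scb-1 (-0.047) for the interaction. Upper quartile scaling lost autophagy (0.0814), chemoreceptors (0.0803), glucuronosyltransferases (0.0592), fbxa (0.0922) and mitochondrial translation (0.149) in N2, and fbxa (0.0599) and mitochondrial translation (0.106) in CB4856. It turned the signs of atfs-1 (0.20, called), COX1 (0.22, called) and ppw-1 (0.051) in N2, and of atfs-1 (0.33, called) and vit-2 (0.21) in CB4856.

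The labels number replicates alike in the 4 groups. Of 18 pairs with the same number 12 had a correlation of deviations over 0.1, with a range of -0.0894 to 0.648. For 8 of 12 libraries the mean correlation with libraries of the other groups was highest for their own number. Both are a hint from the data that same-numbered libraries share some variation. The oocyte mean rose from replicate 1 to 2 to 3 in every group, for example 9.42, 9.47 and 9.59 (log2 CPM) in N2 control. In CB4856 doxycycline it was 7.56, 7.91 and 8.19. With such an order replicate 2 lies near its group mean, so low correlations of its pairs do not argue against shared variation. Because not every pair was over 0.1 and the labels name no shared batch, the main fit did not pair samples by number. Shared variation between same-numbered libraries remains possible. With the number as a replicate block, 2194 genes had the more positive and 1746 the more negative response in CB4856, 2790 were higher in untreated CB4856 and 2391 lower in treated CB4856. The replicate block lost glucuronosyltransferases and fbxa (0.0627) in N2.

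The strand-specific column, which holds fewer reads, gave 230 genes with the more negative response in CB4856. It lost autophagy (0.0633), chemoreceptors (0.148) and fbxa (0.0819) in N2, chemoreceptors (0.138) in CB4856, neurons (0.189) for the interaction and complexes II to IV (0.0541) between untreated strains, and turned atfs-1 (0.027) in CB4856. Without a low-count filter r between the responses was 0.659, chemoreceptors were lost in N2 (0.501) and CB4856 (0.278) and complexes II to IV between untreated strains (0.147), and signs turned for hsp-6 (-0.021) and COX1 (-0.044) in CB4856 and atfs-1 (-0.0046) and glb-5 (-0.0088) for the interaction. With only the compared groups in the fit, chemoreceptors (0.0998) and fbxa (0.0620) were lost in N2, and hsp-6 (-0.0074) and COX1 (-0.030) turned in CB4856.

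With an estimated correlation every list call was lost. In N2 the adjusted p was 0.192 for immune effectors, 0.687 for major sperm proteins and 0.532 for autophagy, body muscle, C-type lectins, chemoreceptors, collagens, glucuronosyltransferases, replication, fbxa, germline, intestine, mitochondrial ribosome, mitochondrial translation, molting, neurons, neuropeptides, oocytes, pharynx, proteasome, spermatogenesis and vitellogenins. In CB4856 it was 0.561 for autophagy, body muscle, major sperm proteins and spermatogenesis, 0.404 for C-type lectins, 0.357 for chemoreceptors, glutathione S-transferases, glucuronosyltransferases, fbxa, immune effectors and mitochondrial ribosome, 0.558 for collagens, 0.512 for replication, germline, neurons, neuropeptides, pharynx and proteasome, 0.530 for intestine, 0.466 for mitochondrial translation and 0.543 for oocytes. For the interaction it was 0.531 for glutathione S-transferases and glucuronosyltransferases and 0.786 for body muscle, cytochromes P450, replication, fatty acid metabolism, germline, major sperm proteins, mitochondrial ribosome, molting, neurons, oocytes, proteasome, spermatogenesis and vitellogenins. Between untreated strains it was 0.830 for complex I, cytosolic ribosome, major sperm proteins, MATH and BTB domain genes, molting, mitochondrial DNA and spermatogenesis, and 0.897 for complexes II to IV, replication and oocytes. Fry lost body muscle and replication (0.183), germline (0.177), major sperm proteins (0.0655), molting, neurons, spermatogenesis and vitellogenins (0.120), oocytes (0.379) and proteasome (0.158) for the interaction, and replication (0.164), molting (0.0577) and oocytes (0.317) between untreated strains.

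Leaving out N2 control and doxycycline replicates 3 together gave 1774 genes with the more positive and 696 with the more negative response in CB4856, and 2647 higher in untreated CB4856. It lost cytochromes P450 (0.0589), neurons (0.196) and oocytes (0.0779) for the interaction. Leave-one-out ranges were 289 to 1720 and 77 to 522 for the more positive and more negative responses, 891 to 1684 for genes higher in untreated CB4856 and 958 to 1749 for genes lower in treated CB4856. For lists in N2 they were autophagy 0.0239 to 0.0514, chemoreceptors 0.0327 to 0.0543, glucuronosyltransferases 0.0256 to 0.0836 and fbxa 0.0310 to 0.0523. For the interaction they were body muscle 0.00523 to 0.0870, cytochromes P450 0.0162 to 0.124, neurons 0.00735 to 0.153, oocytes 1.17e-04 to 0.172 and vitellogenins 3.54e-04 to 0.0674, and glb-5 had -0.51 to 0.61. Between untreated strains they were complexes II to IV 0.0220 to 0.123 and oocytes 0.0170 to 0.101.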

Other observations

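The 143 gene classes below were formed from symbol prefixes with at least 10 measured members, and their tests were chosen after the result was seen. None passed with an estimated correlation, and no class named here changed the sign of its median under 5 other scalings.

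The classes npp, mdt, taf, vps, eif, fbxb and sdz fell with doxycycline. All 25 npp genes, which encode nucleoporins, were lower in N2 (median log2 fold change -0.82, camera adjusted p = 1.63e-07) and in CB4856 (-1.13, 3.23e-08). Of 20 mdt Mediator genes 19 were lower in N2 (-0.89, 9.90e-06) and 19 in CB4856 (-1.08, 2.53e-06), and of 17 taf genes, which encode TBP-associated factors, 16 (-0.83, 1.99e-05) and 17 (-1.22, 4.26e-06). Of 31 vps vacuolar sorting genes 28 (-0.65, 1.41e-06) and 29 (-0.75, 4.74e-07) were lower, and of 25 eif translation initiation genes 23 (-0.34, 7.25e-05) and 25 (-0.67, 7.47e-07). These classes had adjusted p = 0.415 in N2 and 0.416 in CB4856 with an estimated correlation. The F-box class fbxb fell too, with 48 of 56 lower in N2 (-3.37, 1.32e-05; adjusted p = 0.459 with an estimated correlation) and 50 in CB4856 (-4.46, 3.70e-08; adjusted p = 0.419 with an estimated correlation). In untreated CB4856 22 of the 56 were higher than in N2 (median 1.097, 4.26e-07; adjusted p = 0.885 with an estimated correlation). In the class sdz 18 of 24 were lower in N2 (-3.32, 0.00546; adjusted p = 0.466 with an estimated correlation) and 18 in CB4856 (-4.68, 0.00157; adjusted p = 0.424 with an estimated correlation).

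The classes ttr, nlp, twk, nhr, nas and abu rose. Of 56 ttr transthyretin-related genes 40 were higher in N2 (median 0.97, camera adjusted p = 1.04e-04) and 52 in CB4856 (1.17, 3.00e-06), of 65 nlp neuropeptide-like genes 41 (0.59, 7.25e-05) and 56 (0.86, 1.64e-05), and of 40 twk potassium channel genes 26 (0.74, 0.00115) and 36 (1.06, 4.22e-04). Of 183 nhr nuclear receptor genes 103 were higher in N2 (0.56, 0.00540) and 129 in CB4856 (0.82, 4.56e-04). These classes had adjusted p = 0.415 in N2 and 0.416 in CB4856 with an estimated correlation. Of 30 nas astacin protease genes 26 (2.81, 1.04e-04) and 25 (1.98, 0.00168) were higher, with adjusted p = 0.415 and 0.421 with an estimated correlation. All 11 abu genes rose, by a median of 5.97 in N2 (6.94e-04) and 4.202 in CB4856 (0.0290), with adjusted p = 0.417 and 0.517 with an estimated correlation, and no single abu gene was called in the interaction.

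Along the chromosomes the median change with doxycycline in N2 was -0.16 on I, 0.11 on II, -0.17 on III, 0.27 on IV, 0.48 on V and 0.43 on X. In CB4856 it was -0.17, 0.34, -0.15, 0.51, 0.76 and 0.68 in the same order, and these differences were not tested.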
